A study of Mus musculus with 6 samples.

How the data were processed

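RNA was measured by bulk sequencing in 6 libraries of cultured mouse neural crest cells, 3 labelled vagal and 3 labelled sacral. Per the labels' protocols, pieces of neural tube from wild-type C57BL/6 embryos were placed on fibronectin, and the cells that had migrated out after 24 h were collected. Vagal explants came from embryonic day 9.0 embryos at the level of somites 1 to 7, and sacral explants from day 9.5 embryos at the level beyond somite 24. Total RNA was taken with a micro-scale column kit and made into Illumina libraries, per the labels' protocols. The kit's strand setting is not given in the sources used here.

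The authors deposited 1 table per library holding whole-number read counts per gene, not normalized. FastQC, Bowtie2 and the mm10 genome build are named in the submitters' processing notes, with no versions. The counting program and its treatment of reads that match several places are not given in the sources used here. Bowtie2 does not place a read across an intron, so reads over exon junctions and reads shared with processed pseudogenes can be lost or moved. Genes with many such copies, such as Gapdh at 5.78 to 10.8 counts per 1e+06 counts (CPM), can therefore be undercounted. Each table listed 27179 NCBI Gene identifiers, of which 25275 (93.0%) had a symbol in the mouse RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes. Coordinates are from that table, 1-based. The 1904 identifiers without a symbol were kept in the tests and not named.

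Library totals were 24.2 to 38.1 M counts (M, 1e+06), and 17966 to 18534 genes had at least 1 count. For genes with 0 counts in a group, a floor of 3 counts over the group was used, which is 0.0304 CPM for the vagal group. Intervals on count ratios are exact 95% intervals and cover counting error only, because reads are not independent molecules.

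Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, after TMM scaling and its default expression filter, which kept 15452 genes. Fold changes are sacral minus vagal on the log2 scale, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) were computed back from the test, as the absolute fold change over the square root of its F statistic. For genes with few counts in a group they can be smaller than the counting error. CPM values use the TMM-scaled library sizes. Before the data were examined, 40 gene lists, the design, the alternatives and the rule for named genes were written down. Lists with at least 4 tested genes (39 of 40) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run beside it. The list of mitochondrially encoded protein genes was taken by chromosome, because the reference names these genes without the prefix assumed. The list of replication-dependent histone genes was limited to clustered histone symbols, because the pattern fixed for it also took other genes. The Hox gradient is Spearman's rho across Hox genes between paralogue number and log2 fold change, with 1e+05 two-sided permutations. Library values were compared with exact two-sided permutation tests, which cannot give a p below 0.10 with 3 libraries against 3.

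Genes were named by 4 parts of 1 rule. The first took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with a mean of at least 5 CPM and no overlap between groups, without predicted genes and pseudogenes. The second took up to 4 members of each list with the smallest adjusted p. The third took a fixed set of neural crest genes, among them Sox10, Foxd3, Tfap2a, Ret, Ednrb, Pax3 and Twist1, and the last took Xist and 4 Y-linked genes as a check on embryo sex. The genes printed in the text were picked from those given by the rule after their values were seen, and the others are not printed. Any gene outside the rule is said to be chosen after its values were seen.

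The labels number the libraries 1 to 3 in both groups. Deviations from the group means correlated between same-numbered libraries at 0.514, 0.354 and 0.676 over the tested genes, and each library correlated best with its own number. With 3 libraries per group few matchings exist, so such a match can also arise by chance. By the criterion set for pairing (every correlation over 0.1), the numbers were still taken to pair the libraries, on the evidence of the data and not of the labels. The fit with the replicate number as a block is therefore given beside a result where it changes a call or a count. The labels do not say whether the libraries of a group came from separate cultures or litters, so p-values measure the spread between these libraries, which may be technical. Within groups, counts of library pairs differed by far more than sampling noise, with a chi-square per gene of 243 to 692. This is a mean over genes on which the most abundant features weigh most, 1 of which held 1.12 to 18.8% of a library's counts. It is not the noise of a typical gene.

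The tests were run on simulated counts drawn from the real means, library sizes and dispersions of 15452 genes, with 200 genes changed. For sacral against vagal without a block, 4.48% of the genes changed 2-fold, 61.2% of those changed 4-fold and 84.8% of those changed 8-fold were called, beside 6 unchanged genes. With the replicate block, 52.2%, 83.6% and 89.4% of the genes changed 2-fold, 4-fold and 8-fold were called, beside 21 unchanged genes among 171 calls. With no gene changed, the fit without a block called 0 genes and camera called 1 list. That simulation drew each gene independently and without differences by library number, so it gives no false-call rate for camera on these libraries. The other splits of the real libraries into 3 and 3 called 9 to 19 lists. Alternatives were another normalization (RLE, upper quartile), no filter, a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, the replicate block and leaving out each library.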

Results

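Gene expression was compared between vagal and sacral neural crest cells of the mouse, the populations that leave the neural tube at the hindbrain to neck level and at the caudal end of the trunk. Vagal crest gives rise to most of the enteric nervous system, and sacral crest contributes to that of the hindgut. The cells were those that had migrated out of neural tube explants after 24 h of culture, in 3 libraries per group. Library totals were 37.2, 24.2 and 35.8 M counts (M, 1e+06) for vagal libraries 1 to 3 and 27.9, 38.1 and 33.6 M for sacral libraries 1 to 3. The labels place vagal explants at embryonic day 9.0 and sacral explants at day 9.5, so axial level and stage were not separated by the design.

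Sacral cultures expressed posterior Hox genes that were at or near 0 in vagal cultures. These genes encode transcription factors that mark position along the body axis. Of the 15452 genes tested, 8 rose in sacral cultures and 0 fell (edgeR, adjusted p under 0.05), and all 8 lie in Hox clusters: Hoxd13, Hoxd12, Hoxd11, Hoxd10, Hoxc12, Hoxc11, Hoxa11 and the noncoding Hoxa11os. All 8 differed by more than 2-fold. Their mean level was 26.0 to 75.5 CPM in the 3 sacral libraries and at most 0.277 CPM in the 3 vagal libraries, with no overlap between groups in any of them, where chance gives 10% of genes.

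Hoxd11 (gene 15431, chromosome 2, 74679558 to 74687016, mm10) was at 75.5 ± 15.7 CPM in sacral and 0.0986 ± 0.101 CPM in vagal libraries (SD, n = 3 each, edgeR adjusted p = 0.0129). Hoxd10 (gene 15430, 74684273 to 74695106), which overlaps Hoxd11 in the annotation so that their reads may be split, was at 67.1 ± 6.37 against 0.277 ± 0.195 CPM. Hoxd13 (gene 15433, 74668225 to 74671603) was at 26.6 ± 6.36 against 0.0344 ± 0.0298 CPM, a log2 fold change of 9.27 (SE 0.56, edgeR adjusted p = 0.0101). Its 4 vagal counts gave a ratio of 678 with a 95% counting interval of 264 to 2489. Hoxd12 (gene 15432, 74675013 to 74677705) had 0 counts in all vagal libraries and 31.4 ± 10.998 CPM in sacral libraries, which made it at least 1013-fold higher against a floor of 3 counts over the vagal group (edgeR adjusted p = 0.0343). On chromosome 15, Hoxc12 (gene 15421, 102936826 to 102938609) had 2 counts in the vagal group and 32.1 ± 0.807 CPM in sacral libraries, a ratio of 1585 with a 95% counting interval of 438 to 13090. Hoxc11 (gene 109663, 102954526 to 102956701) was at 27.0 ± 2.15 against 0.0336 ± 0.0583 CPM. On chromosome 6, Hoxa11 (gene 15396, 52242105 to 52245810) and Hoxa11os (gene 15397, 52245243 to 52249769) each had 2 counts in the vagal group, and Hoxa11 reached 26.0 ± 8.08 CPM in sacral libraries. These genes overlap on the annotation and the counting is not stated to use strand, so their reads cannot be told apart.

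Of the 12 genes in Hox paralogue groups 10 to 13, 7 rose and 5 did not pass the test over all genes, while all 12 rose when adjusted over the list alone. All 12 were higher in each sacral library than in any vagal library. Hoxa10, Hoxc10, Hoxc13, Hoxa13 and Hoxb13, which lie outside the naming rule and were chosen after their values were seen, did not pass, with Hoxa10 at 92.0 ± 11.5 CPM in sacral and 0.751 ± 0.911 CPM in vagal libraries (edgeR adjusted p = 0.190). As a list, groups 10 to 13 rose (median log2 fold change 8.61, or 8.67 from count ratios with the gene at 0 counts set to its bound, camera adjusted p = 5.91e-72, and adjusted p = 0.00735 with an estimated correlation). With the replicate block the list passed at the preset correlation (camera adjusted p = 9.66e-35) and not with an estimated one (0.381) or with fry (0.137, against 0.00144 without the block). Summed over the 12 genes, the level was 599 ± 66.6 CPM in sacral and 4.25 ± 4.63 CPM in vagal libraries. Without vagal library 1, vagal library 2, sacral library 1 or sacral library 2 edgeR called 3, 1, 0 and 0 genes in place of 8, with 282 and 288 genes at an unadjusted p under 0.05 where none was called. Beside the 0 genes that fell, 78 lower genes had an unadjusted p under 0.05, limma voom called 0 lower genes and DESeq2 called 6. The counts at an unadjusted p under 0.05 are each below the share of 0.05 of tested genes that chance alone would give. They are therefore not read as further differences. DESeq2 with the replicate block, chosen after seeing the data, called 157 higher and 121 lower.

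**Figure D1:**
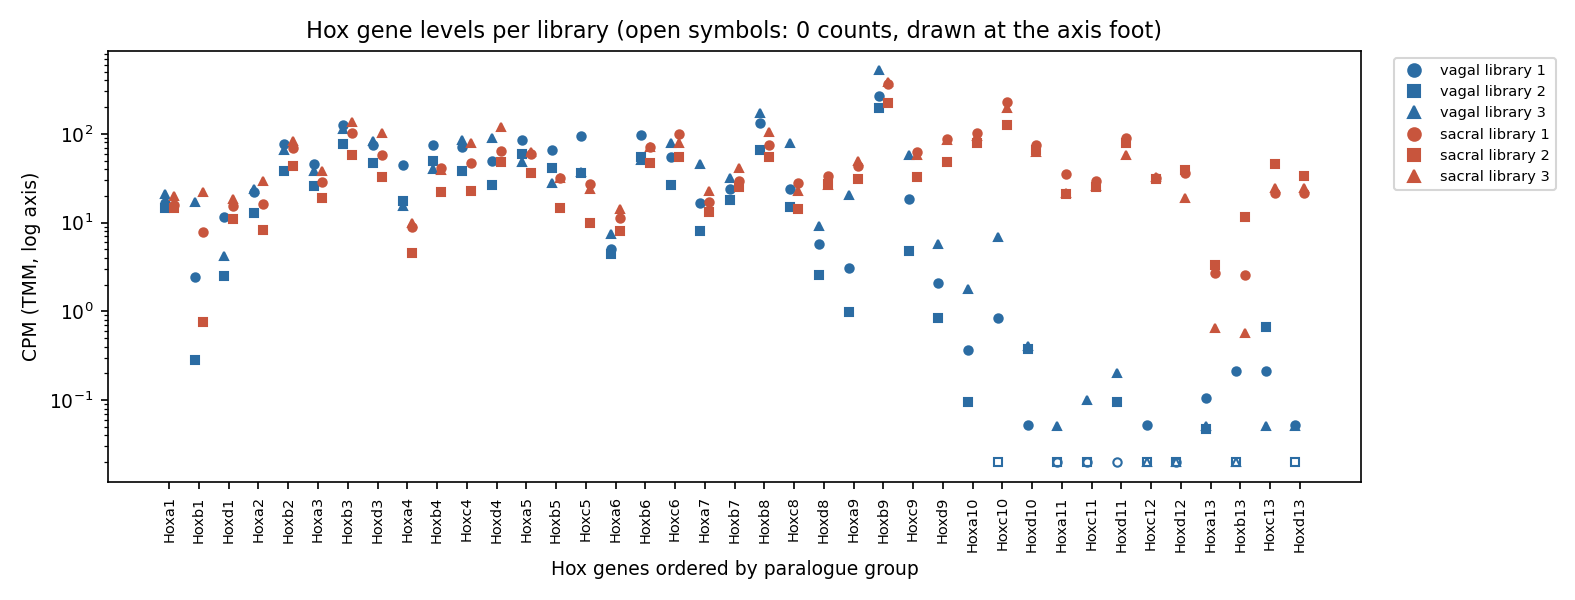
CPM of the 39 Hox genes in each library on a log axis, ordered by paralogue group, with vagal libraries in blue, sacral libraries in red and symbol shape giving the library number. Vagal and sacral points overlap for most genes of groups 1 to 8, and for groups 10 to 13 all sacral points lie above all vagal points.

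Anterior and middle Hox genes were expressed in both groups. No member of groups 1 to 5 (15 genes) or 6 to 9 (12 genes) passed the test over all genes, and 0 of groups 1 to 5 and 2 of groups 6 to 9 passed when adjusted over the list alone. With the replicate block, 3 rose and 3 fell in groups 1 to 5 and 7 rose and 1 fell in groups 6 to 9 when adjusted over the list alone, and Hoxd9 rose over all genes. In groups 1 to 5, Hoxa4 was at 7.87 ± 2.90 CPM in sacral and 25.9 ± 16.4 CPM in vagal libraries, and Hoxc5 at 20.3 ± 9.21 against 56.4 ± 33.7 CPM (edgeR adjusted p = 1 for both). In groups 6 to 9, Hoxd9 was at 73.4 ± 22.0 against 2.91 ± 2.56 CPM, Hoxd8 at 28.9 ± 3.74 against 5.77 ± 3.27 CPM and Hoxa9 at 41.1 ± 9.02 against 8.25 ± 10.8 CPM. Camera called groups 1 to 5 lower (median log2 fold change -0.14, adjusted p = 0.00607) and groups 6 to 9 higher (median 0.46, adjusted p = 4.68e-06), and neither held with an estimated correlation (adjusted p = 0.728 and 0.688). With the replicate block, groups 1 to 5 no longer passed (adjusted p = 0.0623). The call for groups 1 to 5 was also lost without vagal library 1 (0.210), vagal library 3 (0.114) or sacral library 2 (0.654, opposite direction). Across all 39 Hox genes, log2 fold change increased with paralogue number (Spearman's rho = 0.688, permutation p = 1e-05, the smallest that the permutations can give). This correlation is across genes, which are not independent replicates. Much of it restates the rise of groups 10 to 13 (median log2 fold change 8.61), and an increase within groups 1 to 9 alone was not tested.

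With the replicate number as a block, 13 genes rose and 4 fell in sacral cultures (edgeR), a count of 17 that includes the 8 genes above. Outside the Hox clusters, Bmp4, a secreted growth factor, and Krt19, a keratin of simple epithelia, rose. Cxcl12, a chemokine that guides migrating cells, Tbx3, a T-box transcription factor, Bgn, which encodes the matrix proteoglycan biglycan, and Tll1, a metalloprotease of the tolloid family, fell. Hoxc13, Hoxd9 and Hoxa10 were the other genes gained. Hoxc13, Hoxa10, Bgn and Tll1 lie outside the naming rule and were chosen after their values were seen.

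Bmp4 (gene 12159, chromosome 14, 46383525 to 46390669) was at 73.4 ± 12.003 CPM in sacral and 25.1 ± 9.02 CPM in vagal libraries (SD, n = 3 each), with a blocked log2 fold change of 1.59 (SE 0.14, edgeR adjusted p = 0.0435). Krt19 (gene 16669, chromosome 11, 100140810 to 100145926) was at 148 ± 74.4 against 39.4 ± 15.2 CPM (blocked edgeR adjusted p = 0.0296). Cxcl12 (gene 20315, chromosome 6, 117168535 to 117181368) was at 41.4 ± 31.8 CPM in sacral and 215 ± 182 CPM in vagal libraries, with a blocked log2 fold change of -2.35 (SE 0.17, edgeR adjusted p = 0.0226). Tbx3 (gene 21386, chromosome 5, 119670534 to 119684724) was at 14.1 ± 6.43 against 41.6 ± 15.4 CPM, and Tll1 (gene 21892, chromosome 8, 64013098 to 64206008) at 14.1 ± 4.72 against 48.6 ± 23.3 CPM. Bgn (gene 12111, chromosome X, 73483601 to 73495936) was at 91.1, 92.0 and 10.2 CPM in sacral libraries 1 to 3 and 300.5, 324 and 44.0 CPM in vagal libraries 1 to 3. All 6 genes differed in the same direction in 3 of 3 numbered pairs. A call in the blocked fit favours such agreement, so it is no separate support. None of the 6 passed without the block in edgeR (adjusted p = 0.837 for Bmp4 and 1 for the other 5), while Bmp4 passed without it in DESeq2 (adjusted p = 0.000831). The blocked count was 2, 32 and 14 genes after leaving out the libraries numbered 1, 2 and 3 of both groups. Without number 1 none of the 6 genes passed (edgeR adjusted p = 0.0923 to 0.260). Without number 2 all but Tbx3 (0.0560) passed, and without number 3 only Krt19 (0.0348) and Cxcl12 (0.0327) did.

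**Figure D2:**
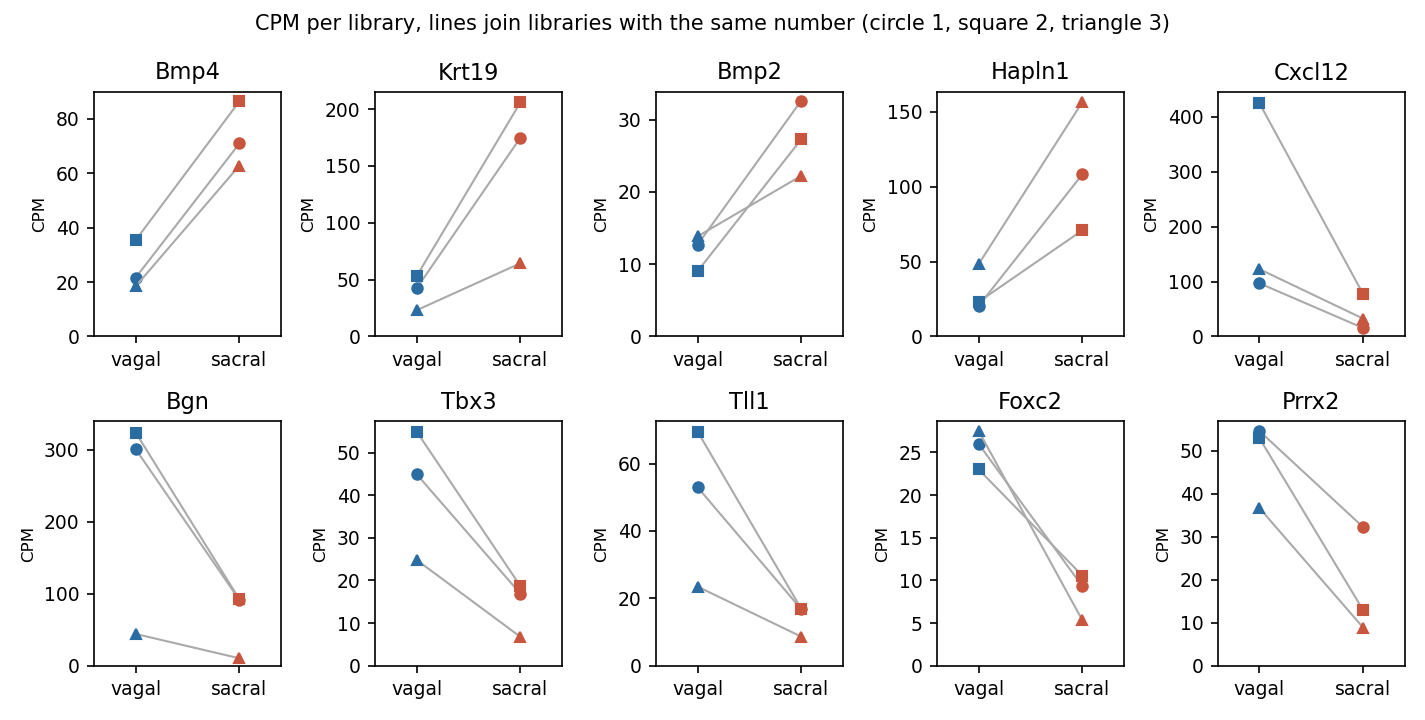
CPM of 10 genes per library on a linear axis from 0, with lines joining vagal and sacral libraries of the same number. Bmp4, Krt19, Bmp2 and Hapln1 are higher in sacral in all 3 pairs, and Cxcl12, Bgn, Tbx3, Tll1, Foxc2 and Prrx2 are lower in all 3.

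Camera at the preset correlation called the enteric and autonomic lists lower in sacral cultures, without any member passing over all genes unless the block was used. Summed CPM of the enteric list overlapped between groups, at 1307, 1780.5 and 1592 in vagal libraries 1 to 3 and 779, 1909.5 and 1204 in sacral libraries 1 to 3. In all 3 pairs, 6 enteric members were lower and 1 higher. The autonomic sums did not overlap, at 225, 220 and 194 in vagal and 107, 119 and 136 in sacral libraries. Of 17 enteric neural crest genes, 0 rose, 0 fell and 17 did not pass, with none past the threshold when adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 1.66e-05, and adjusted p = 0.447 with an estimated correlation). Of 12 autonomic neuron genes, 0 passed over all genes or when adjusted over the list alone (median -0.77, camera adjusted p = 4.42e-06, and adjusted p = 0.258 with an estimated correlation). With the replicate block, 2 enteric and 3 autonomic genes fell when adjusted over the list alone, and the enteric gene Tbx3 fell over all genes (edgeR adjusted p = 0.0466). Hand2, a transcription factor of the sympathetic and enteric lineages, was at 3.68 ± 2.61 CPM in sacral and 15.2 ± 11.2 CPM in vagal libraries (edgeR adjusted p = 1). Gata2 was at 9.10 ± 3.97 against 27.6 ± 13.9 CPM, and Ret, the receptor for glial cell line-derived neurotrophic factor, at 16.1 ± 8.17 against 33.6 ± 15.1 CPM. Ret was lower in sacral in 2 of 3 numbered pairs. Without sacral library 1 the enteric list no longer passed (camera adjusted p = 0.159).

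Early neural crest genes were expressed in every library. Sox10, a transcription factor that marks migrating crest, was at 340, 429 and 357 CPM in vagal libraries 1 to 3 and 112, 536 and 179 CPM in sacral libraries 1 to 3 (edgeR adjusted p = 1). Foxd3 was at 81.5 ± 52.2 CPM in sacral and 104 ± 23.8 CPM in vagal libraries, Tfap2a at 53.4 ± 33.9 against 67.7 ± 2.66 CPM, Twist1 at 18.0 ± 8.54 against 25.8 ± 8.92 CPM and the endothelin receptor gene Ednrb at 210 ± 175 against 201 ± 105 CPM. Pax3 was at 135 ± 53.4 against 89.3 ± 34.1 CPM and was higher in sacral in 3 of 3 numbered pairs. Snai1 was at 20.6 ± 8.01 against 35.8 ± 5.75 CPM, and Erbb3 at 127 ± 70.9 against 187 ± 30.7 CPM. Of the 20 neural crest specifiers, 0 passed over all genes or when adjusted over the list alone, and camera called the list lower (median log2 fold change -0.17, adjusted p = 0.00593, and adjusted p = 0.493 with an estimated correlation). When adjusted over the list alone, 1 specifier rose and 1 fell with the replicate block. The list did not pass without the libraries numbered 3 (0.15), vagal library 3 (0.0643), sacral library 1 (0.0944) or sacral library 3 (0.0777).

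Camera called ectomesenchyme genes, which mark crest that forms connective tissue and skeleton of the head, lower in sacral cultures as a list. Of 18 members, 0 rose and 0 fell over all genes, and 1 rose and 1 fell when adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 5.23e-07, and adjusted p = 0.447 with an estimated correlation). When adjusted over the list alone, 1 rose and 5 fell with the replicate block, and Tbx3 fell over all genes. Foxc2, a forkhead transcription factor, was at 8.41 ± 2.73 CPM in sacral and 25.5 ± 2.30 CPM in vagal libraries, and the homeobox gene Prrx2 at 18.0 ± 12.5 against 48.1 ± 9.91 CPM (edgeR adjusted p = 0.837 and 1).

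Lists of tail bud and epithelial genes were at higher levels in sacral cultures, and melanoblast genes were high in sacral library 2. Of 10 tail bud and neuromesodermal progenitor genes, 0 passed over all genes or when adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 0.000136, and adjusted p = 0.297 with an estimated correlation). Cdx2, a homeobox gene of the posterior axis, was at 33.4, 3.30 and 5.26 CPM in sacral libraries 1 to 3 and at most 1.16 CPM in vagal libraries, and Nkx1-2 at 2.44 ± 1.10 against 0.548 ± 0.584 CPM. The mesodermal gene T (brachyury) was at 83.8 CPM in sacral library 2 and 0.376 to 8.85 CPM in the other 5 libraries.

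Of 12 epithelial and surface ectoderm genes, 0 passed over all genes and 2 rose when adjusted over the list alone (median log2 fold change 2.70, camera adjusted p = 7.63e-09, and adjusted p = 0.447 with an estimated correlation). The block gave 3 that rose when adjusted over the list alone, and Krt19 rose over all genes. The median member was at 44.3 CPM in sacral library 2 and at 1.36 to 4.93 CPM in the other 5 libraries. Cldn6, a tight junction gene, was at 3.30, 52.0 and 3.79 CPM in sacral libraries 1 to 3 and at most 0.706 CPM in vagal libraries. Epcam, an epithelial adhesion gene, was at 20.6 CPM in sacral library 2 and at most 2.28 CPM in the other 5. Without sacral library 2 the list still passed (camera adjusted p = 1.01e-05). Of 9 melanoblast genes, 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0159, and adjusted p = 0.728 with an estimated correlation). None of the 9 was higher in sacral in all 3 pairs. Sacral library 2 held the highest levels of Dct (112 CPM, against 2.44 to 24.7 CPM in the other 5) and Pmel (182 CPM, against 11.2 to 47.2 CPM), both genes of pigment synthesis. The melanoblast list did not pass without sacral library 2 (adjusted p = 0.697, opposite direction), vagal library 2 (0.107), vagal library 3 (0.159) or the libraries numbered 3 (0.0523).

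**Figure D3:**
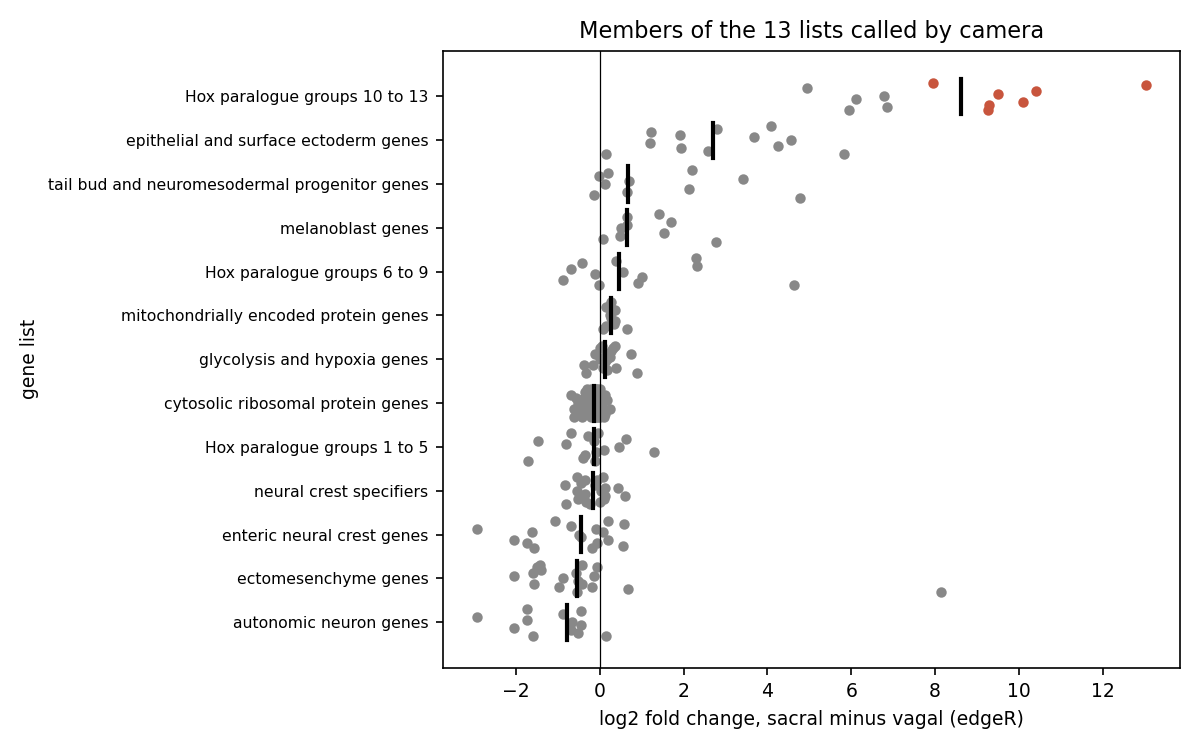
Log2 fold change (sacral minus vagal, edgeR) of each member of the 13 gene lists called by camera at the preset correlation, with black bars at the list medians and red points for genes with an adjusted p under 0.05. The 7 red points are all in Hox groups 10 to 13.

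Among genes of secreted signals, guidance and matrix, Bmp4 rose and Cxcl12 fell with the block, and no other member of these lists passed over all genes in edgeR. Of 16 BMP pathway genes, 0 passed over all genes and 3 rose when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0974, with a mean log2 fold change of 0.21 and a median of -0.20). Beside Bmp4, Bmp2 was at 27.4 ± 5.21 CPM in sacral and 11.9 ± 2.52 CPM in vagal libraries, Bmp7 at 30.3 ± 14.2 against 12.2 ± 4.33 CPM and the BMP-binding protein gene Bmper at 44.3 ± 8.49 against 20.7 ± 6.06 CPM. Sema3a, a repulsive guidance ligand, was at 80.4 ± 34.6 against 26.7 ± 2.94 CPM, and Hapln1, a link protein of hyaluronan matrix, at 112 ± 42.9 against 30.5 ± 15.4 CPM. Wnt4 was at 63.4 ± 5.99 against 27.4 ± 12.7 CPM, and the cadherin gene Cdh3 at 31.6 ± 18.2 against 10.3 ± 2.52 CPM. None of these 7 genes passed without the block (edgeR adjusted p = 1) or with it (0.0615 for Hapln1 and at least 0.227 for the others). Each was higher in sacral in 3 of 3 numbered pairs, which the choice of members by small p favours. Other members were lower in sacral: the proteoglycan gene Dcn was at 3.65 ± 2.96 CPM in sacral and 11.2 ± 8.04 CPM in vagal libraries, and the guidance ligand gene Slit1 at 49.4 ± 15.8 against 83.3 ± 32.2 CPM (edgeR adjusted p = 1 for both). In all 3 pairs, 3 matrix genes were higher and 9 lower, 5 guidance genes higher and 8 lower, and 5 BMP genes higher and 5 lower. When adjusted over the list alone with the block, 1 matrix gene rose and 6 fell, and 1 guidance gene rose and 2 fell. Camera did not call the lists of guidance genes (adjusted p = 0.429), extracellular matrix genes (0.645), Wnt pathway genes (0.0665) or integrins and cadherins (0.878).

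Housekeeping lists moved little. Camera called 79 cytosolic ribosomal protein genes lower (median log2 fold change -0.13, adjusted p = 4.6e-06, and adjusted p = 0.700 with an estimated correlation), with Rps26 at 166 ± 29.4 CPM in sacral and 255 ± 58.2 CPM in vagal libraries. It called 19 glycolysis and hypoxia genes higher (median 0.14, adjusted p = 0.0266, and adjusted p = 0.447 with an estimated correlation), with Egln3, a prolyl hydroxylase gene induced by low oxygen, at 15.0 ± 4.11 against 8.06 ± 0.940 CPM. The 12 mitochondrially encoded protein genes were also called higher (median 0.26, adjusted p = 0.00935, and adjusted p = 0.728 with an estimated correlation). In these lists 0 genes passed over all genes or when adjusted over the list alone. The ribosomal protein call was lost without sacral library 2 (0.232), and the glycolysis call without vagal library 2 (0.107), vagal library 3 (0.217), sacral library 1 (0.491) or the libraries numbered 3 (0.114). The mitochondrial call was lost without vagal library 1 (0.210), vagal library 3 (0.335), sacral library 3 (0.529) or the libraries numbered 3 (0.936, opposite direction). The replication-dependent histone list was not called (51 genes, adjusted p = 0.861). In total 13 of 39 lists were called, 7 higher and 6 lower, and 1 of them, Hox groups 10 to 13, held with an estimated correlation, though not with the block added (0.381). With the replicate block camera also called erythroid genes (adjusted p = 0.0122), G2 and M phase genes (0.00427) and S phase genes (0.0342) higher and Notch pathway genes (0.0220) lower. None of these 4 held with an estimated correlation and the block (adjusted p = 0.701 for erythroid genes and 0.718 for the other 3).

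Lists for the remaining cell types that an explant could hold showed no call between groups without the block. Camera gave adjusted p = 0.169 for neural tube progenitor genes, 0.856 for somite genes, 0.726 for lateral and intermediate mesoderm genes, 0.247 for endoderm and notochord genes, 0.0665 for endothelial genes and 0.0665 for erythroid genes. Only 3 myeloid genes passed the expression filter, so that list was not tested. The neural tube progenitor list had a median of 43.9 and 27.3 CPM in vagal and sacral library 3, 18.6 CPM in sacral library 2 and 4.04 to 5.69 CPM in the other 3 libraries.

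**Figure D4:**
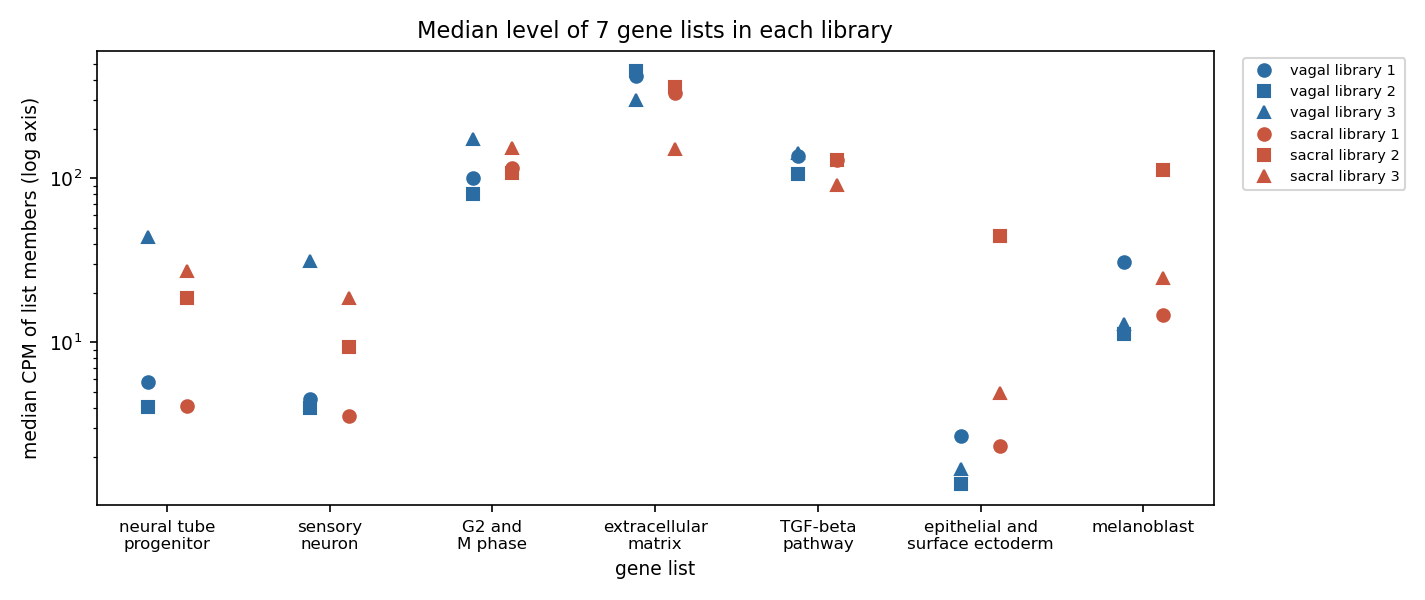
Median CPM over the members of 7 gene lists in each library, on a log axis, with vagal libraries in blue, sacral libraries in red and symbol shape giving the library number. Both libraries numbered 3 are highest for neural tube progenitor and sensory neuron genes, and sacral library 2 is highest for epithelial and melanoblast genes.

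The largest spread among libraries did not follow the groups. The first principal component of log2 CPM held 46.3% of the variance and placed both libraries numbered 3 apart from the other 4, and the next held 20.1%. Spearman's correlations of log2 CPM across genes were 0.968 to 0.987 between same-numbered libraries of different groups and 0.936 to 0.977 between libraries of 1 group. No library value differed between groups in exact permutation tests, in which the smallest p possible is 0.10: total count (p = 0.80), genes detected (p = 0.30), share of counts in the 100 most abundant genes (23.0 ± 9.72% in sacral and 23.1 ± 10.6% in vagal, p = 0.90), ribosomal protein share (p = 0.80) and mitochondrially encoded protein share (p = 0.40). Identifiers without a symbol held 1.888 and 1.745% of the counts in vagal and sacral library 3 and 6.39 to 22.0% in the other 4, most of them in a single feature. As a check on embryo sex, Xist was at 224 to 498 CPM and the Y-linked gene Ddx3y at 29.7 to 47.1 CPM in all 6 libraries.

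**Figure D5:**
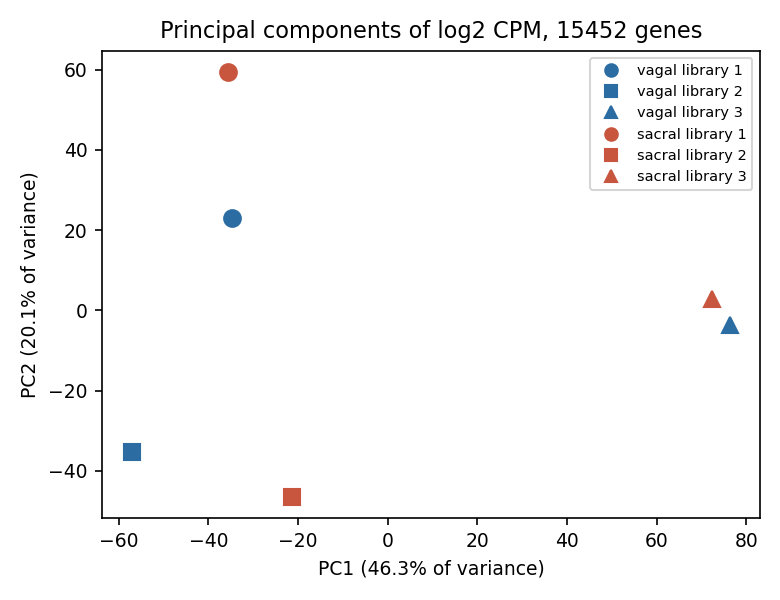
First and second principal components of log2 CPM over 15452 genes for the 6 libraries, vagal in blue and sacral in red, with symbol shape giving the library number. Both libraries numbered 3 lie at the right, and same-numbered libraries lie nearer to each other than to most libraries of their group.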

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

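The settings below that pair DESeq2, voom, fry or the estimated correlation with the replicate block, leave out the libraries of a number in both groups or leave out ribosomal RNA features were chosen after seeing the data. As ribosomal RNA features, that setting left out all 1904 identifiers without a symbol, Lars2 and mitochondrial ribosomal RNA genes, not all shown to be ribosomal RNA. The 8 genes, each also over 2-fold, stayed 8 with RLE or upper quartile scaling, no filter, the strict filter or without ribosomal RNA features, and voom called 7. DESeq2 called 39, and leaving out each library in turn gave 0 to 9, 7 with sacral library 3 left out. The replicate block gave 17 with edgeR and 17 with voom, and 278 with DESeq2, 167 of them over 2-fold. Without the libraries numbered 3, 5 genes were called with no block. With the block, leaving out number 1, 2 or 3 gave 2, 32 and 14 genes. The causes were not tested, beyond the fewer libraries in the fits that leave some out.

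The 13 called lists became 1 with an estimated correlation, 1 with fry, and 0 for each of these with the replicate block. They were 20 with the block and without number 2, and 15 to 18 when each library was left out. The Hox gradient passed in all settings run, with rho from 0.664 to 0.748 (0.673 to 0.735 leaving out each library, 0.709 with the block).

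Ednrb changed sign from 0.07 to -0.35 with voom, -0.32 with the block, -0.31 and -0.24 with the block in DESeq2 and voom, and -0.68 and -0.47 with the block and without number 2 or 3. Leaving out 1 library gave -0.71 to 0.57 for it. Pmel changed sign to -0.42 without sacral library 2 and -0.62 with the block and without number 2 (-0.42 to 2.38 leaving out each library). The set tests of Hox groups 1 to 5 (0.654) and melanoblast genes (0.697) changed direction without sacral library 2 (2.91e-06 to 0.654 and 1.21e-05 to 0.697 leaving out each library), the melanoblast test also with the block and without number 2 (0.258), and that of mitochondrially encoded genes without number 3 (0.936). Removing mitochondrially encoded genes from library totals changed no comparison of library values. At 24.2 to 38.1 M counts, depth limited the folds of Hoxd12, Hoxc12 and Hoxa11, which had 0 to 2 counts over the vagal group.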

Other observations

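The test of genes by replicate number, the Hox check on sacral library 2 and the test on Hoxb9 were chosen after the results they bear on had been seen.

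Some genes varied with the library number, and the genes named in this paragraph were chosen after their values were seen. Several genes of early neurogenesis were highest in both libraries numbered 3. Neurog2 was at 92.8 and 50.4 CPM in vagal and sacral library 3 and 4.98 to 21.6 CPM in the other 4, Neurod4 at 77.0 and 54.7 against 3.99 to 10.97 CPM, and Prdm12, a gene of sensory neuron precursors, at 54.3 and 19.3 against 0 to 4.49 CPM. The neural tube genes Pax6 (80.8 and 87.0 against 9.77 to 29.5 CPM) and Hes5 (87.2 and 51.2 against 3.95 to 18.6 CPM) did the same. Other neural tube genes did not: Olig2 was at 45.1 and 6.64 CPM, with 9.34 CPM in sacral library 2, and Nkx6-1 at 44.2 and 11.7 CPM, with 19.98 CPM in sacral library 2. The embryonic globin gene Hbb-y was at 17.6 and 47.5 CPM there, 13.2 CPM in sacral library 2 and at most 0.212 CPM in the other 3, and was higher in sacral in all 3 pairs. The matrix-related genes Mmp2 and Spp1 were lowest in these libraries, where the summed CPM of the matrix list was 10000 and 7884 against 19973 to 21727. Vcan did not follow this, at 379 CPM in vagal library 3, its highest level, and 195 CPM in sacral library 3. Summed G2 and M phase genes were highest there (4147 and 3883 against 1946.5 to 2671 CPM), and so were S phase genes (3798 and 3507 against 1650.1 to 2531 CPM). Mmp2 was at 374, 475 and 68.6 CPM in vagal libraries 1 to 3 and 210, 244 and 24.5 CPM in sacral libraries 1 to 3, so it was also lower in sacral in all 3 pairs (blocked log2 fold change -1.09, SE 0.15, edgeR adjusted p = 0.162). Spp1 was at 3.25 and 3.58 against 39.1 to 54.0 CPM.

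With the group as a term, 2432 of 15452 genes differed by replicate number (edgeR, adjusted p under 0.05), against 17 by group in the same model. Without the ribosomal RNA features defined above, 2507 genes differed. TMM scaling trims extreme features in either case, so this test could not decide whether they acted through scaling. The tables argue against a trend with transcript length or GC content. After its removal limma called 2423 genes, against 2843 before, with values for 95.9% of the genes concerned. Library values split the same way: in vagal and sacral library 3, mitochondrial ribosomal RNA held 0.0324 and 0.0512% of counts against 0.510 to 1.42% in the other 4, the most abundant feature 1.25 and 1.12% against 5.555 to 18.8%, and the 100 most abundant genes 14.25 and 14.22% against 20.07 to 34.85%. Whether RNA or library preparation, the share of neural tube cells or another source lies behind this stays open, and no biological explanation was tested.

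Sacral library 2 stood apart by epidermal genes, those named here chosen after their values were seen: Krt14 was at 104 CPM, Krt5 at 56.9 and Trp63 at 18.3, against at most 18.3, 1.87 and 1.71 CPM in the other 5. Epidermal cells carried with the explant may account for the high epithelial genes of sacral library 2. They do not account for Krt19 in sacral library 1, at 175 CPM, where Krt14 and Trp63 were at 0 CPM and Krt5 at 0.169 CPM. Nor do they cover the call of the epithelial list without sacral library 2 (camera adjusted p = 1.01e-05). In a second list of 20 epidermal genes, none of them in another list, written before its values were seen, 15 were tested, 12 were highest in sacral library 2, and the median log2 ratio to the mean of the other 5 was 2.21 (with 0.1 CPM added). Endoderm and notochord genes were highest there too, with a list sum of 139 CPM against 9.36 to 30.9 CPM and Shh at 95.97 against 3.09 to 19.6 CPM, and the source of these was not tested. A wrong sacral label is argued against, since the summed CPM of Hox groups 10 to 13 was 0.905 times the mean of the other 2 sacral libraries.

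Hoxb9, chosen with Hoxb8 after their values were seen, was the most abundant Hox gene in vagal cultures, at 327 ± 170 CPM against 324 ± 87.5 CPM in sacral (SD, n = 3 each). Hoxb8 was at 124 ± 54.2 against 77.7 ± 24.7 CPM. Neither passed the edgeR test. Sacral cells mixed into the vagal cultures are argued against by Hox groups 11 to 13, whose summed level in vagal was 0.00252 of that in sacral, while the ratio for Hoxb9 was 1.01. Expression by the vagal cells themselves, reads of other group 9 genes counted for Hoxb9 and trunk-level tissue in the vagal explants stay open and were not tested.

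Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 8 genes, at any size and at 2-fold or more, and the highest of the others 0, so 1 split gave as many. For gene lists the real split called 13 and the highest other 19, and 7 splits called as many. The 3 other splits that part all pairs gave 0 genes and up to 19 lists. With the block, 1 of 4 assignments of labels within pairs gave 17 genes, and the highest of the others gave 0. These numbers of splits are too few for a share under 0.05.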
